A study of Mus musculus with 18 samples.

How the data were processed

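Polyadenylated RNA was measured in snap-frozen pancreas from 18 mice aged 20 weeks. Per the labels, total RNA was primed at the poly(A) tail with an oligonucleotide that carried an index of 8 bp for the sample and a unique molecular identifier (UMI) of 10 bp. The samples were pooled, amplified by template switching and fragmented with a transposase. A UMI marks each captured molecule, so that copies made by PCR can be told from separate molecules. The deposited table holds whole-number counts per gene, not normalised, for 25651 genes in 18 libraries, and the values of 18 of 18 count columns were whole numbers. The authors named the table as counts of UMIs. The aligner, the rule by which UMIs were collapsed and the annotation release are not given in the sources used here. Per the submitters' processing notes, the authors worked with genome builds GRCm38 and mm10, R 4.1.2, edgeR 3.36.0 and limma 3.50.0. Gene symbols and positions were taken from the deposited table. Of its gene identifiers, 25575 are in GENCODE M21, and the start position equals the one given there for 25436.

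Each library is 1 mouse, and each library's group was taken from the genotype in its label, which gave 6 wild-type (WT) mice, 7 KPC mice and 5 KPC ASC KO mice. The labels give no sex, litter, batch or histology. The mouse numbers are not shared between groups, so no pairing was used. Library totals ran from 294077 to 1626977 counts. A gene at 10 counts in a library of 294077 counts is measured only roughly, and 6920 genes passed the filter on low counts. Between libraries of the same group, the counts of every pair differed by more than sampling noise (lowest chi-square per degree of freedom 2.35), so no library is a copy of another in its group.

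The counts as deposited were analysed here with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its usual minimum count of 10 in at least the smallest group of 5 mice, and libraries were scaled by trimmed mean of M values (TMM). The quasi-likelihood F test was fitted to all 18 mice in 3 groups with robust estimation and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the 6920 genes. A gene was called changed at an adjusted p under 0.05. Values per gene are given as TMM-normalised CPM, with the SD between mice, and as log2 fold changes with their standard errors. The 3 comparisons were KPC against WT, KPC ASC KO against KPC and KPC ASC KO against WT.

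Before the data were examined, 49 gene lists for pancreas, stromal and immune cell types, innate immunity, tumour pathways and RNA quality were fixed, together with the tests, the rule for named genes and the alternatives. Lists with at least 5 tested genes, 36 of the 49, were tested with fry in limma 3.58.1 on voom values of the same genes, with adjustment over the 36 lists. The directional p-value of fry asks whether the genes of a list move on balance one way, and does not compare the list with other genes. Each list's count of changed members is given over all genes tested and adjusted over the list alone. Calls of lists were also computed with camera, at its preset correlation of 0.01 and at an estimated correlation. For each mouse, the score of a list is the mean log2 CPM, with a prior count of 2, of its tested members. Groups were compared by an exact two-sided permutation test with adjustment over 48 lists that had at least 1 tested gene. The share of counts taken by acinar enzyme genes, summed CPM of immune cell lists (a share of all counts, without TMM scaling) and measures of library quality were compared by the same exact test, with adjustment over 36 tests.

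The named genes follow the rule fixed beforehand. Pycard and Trp53 are named whatever their result. Then come changed genes with a mean of at least 10 CPM in the higher group, in order of absolute log2 fold change and up to 10 in each direction. Left out are predicted genes, Xist and Y-linked genes, mitochondrially encoded genes and immunoglobulin or T cell receptor segments, the last of which are counted as a class. From each list that passes, up to 4 members with the smallest p-values are named whether or not they pass. Where no gene passes, the 5 with the smallest p-values are named. The rule asks for about 30 names per comparison, and the KPC against WT comparison goes above that because 15 lists passed and each is given with its first members.

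The test was run on simulated counts for the 6920 genes at the real library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For KPC against WT it recovered 32 of the 100 changed 2-fold and 91 of the 100 changed 4-fold, with 4 false calls. For KPC ASC KO against KPC it recovered 42 and 87, with 7 false calls. For KPC ASC KO against WT it recovered 19 and 74, with 3 false calls. None of 20 unchanged simulated lists was called in any of the 3 comparisons by fry. The simulated genes were drawn independently of each other, so this does not cover lists whose genes vary together between mice.

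The alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings (DESeq2 size factors, upper quartile, total counts, and TMM without the acinar enzyme genes). Further ones were no filter and a stricter filter at a count of 30, fits of only the compared groups, a sex-linked score or the acinar enzyme level as a covariate, and leaving out each mouse in turn. Alternatives added after seeing the data were leaving out KPC mice 40, 89, 145 and 154, thinning all libraries to 294077 counts, the B cell level as a covariate for genes and for lists, and a list test on all genes with at least 10 counts in total. Overlap between comparisons that share a group was set beside 50 simulations of unchanged groups, and beside splits of the shared mice. Each count of calls was also compared with 100 splits of the mice into groups of the same sizes, the real one included, drawn with seed 1. No sample was left out of the main comparisons.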

Results

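Gene expression was measured in pancreas from 18 mice aged 20 weeks, bred from 129Sv and C57BL/6 strains, in 6 wild-type (WT) mice, 7 mice labelled KPC and 5 mice labelled KPC ASC KO. KPC is the usual name of a mouse model of pancreatic cancer, although the labels do not spell it out. ASC, encoded by Pycard, is the adaptor protein through which inflammasome sensors recruit caspase 1. The WT libraries held 416879 counts in mouse 69, 408070 in mouse 1197, 304142 in mouse 1202, 319058 in mouse 1213, 294077 in mouse 1237 and 389118 in mouse 1238. The KPC libraries held 682574 counts in mouse 40, 1626977 in mouse 43, 452472 in mouse 48, 1020527 in mouse 89, 949689 in mouse 145, 917213 in mouse 154 and 518768 in mouse 210. The KPC ASC KO libraries held 647947 counts in mouse 318, 424289 in mouse 335, 550873 in mouse 377, 482464 in mouse 384 and 374432 in mouse 388. The mean total was 355224 ± 55496 (SD, n = 6) in WT, 881174 ± 395011 (SD, n = 7) in KPC and 496001 ± 107475 (SD, n = 5) in KPC ASC KO. The KPC and WT totals differed (exact two-sided permutation test, p = 0.0035, adjusted p = 0.018 over 36 tests). A mean of 12528 genes was detected in WT, 17952 in KPC and 14184 in KPC ASC KO libraries.

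The targeted gene was examined first. Pycard (ENSMUSG00000030793), on chromosome 7 at 127989708 to 127993867 of GRCm38, stood at 58.6 ± 6.95 CPM (SD, n = 6) in WT, 70.0 ± 24.2 CPM (SD, n = 7) in KPC and 19.9 ± 11.7 CPM (SD, n = 5) in KPC ASC KO pancreas. All 5 KPC ASC KO mice, at 5.56 to 34.2 CPM, lay below all 7 KPC mice, at 35.1 to 99.5 CPM, and below all 6 WT mice, at 45.4 to 65.5 CPM. The log2 difference between KPC ASC KO and KPC was -1.94 (SE 0.35, adjusted p = 0.0043), and an exact two-sided permutation test gave p = 0.00126 (adjusted p = 0.00325 over 3 tests). Against WT the log2 difference was -1.67 (SE 0.38), which did not pass over all genes in edgeR (adjusted p = 0.14) but passed as a single value in the exact test (p = 0.00216, adjusted p = 0.00325). The depth behind these values is 3 to 12 counts per KPC ASC KO library, against 9 to 19 in WT and 23 to 166 in KPC. The labels do not say which part of the gene was removed, and tags from the 3' end can lie outside it, so the remaining counts do not measure intact transcript. The call against KPC was lost without KPC mice 40, 89, 145 and 154, an alternative chosen after seeing the data (-1.31, adjusted p = 0.144). Between KPC and WT, Pycard was not called changed (log2 0.26, adjusted p = 0.519), but this depends on scaling, as under total counts it was higher in KPC (1.61, adjusted p = 0.0002). The difference turned to -0.36 (adjusted p = 0.526) without those 4 mice and to -0.19 (adjusted p = 0.674) with the B cell level as a covariate.

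Trp53, which encodes the tumour suppressor p53, was higher in KPC at 27.9 ± 6.29 CPM (SD, n = 7) than in WT at 10.0 ± 6.55 CPM (SD, n = 6), a log2 difference of 1.48 (SE 0.41, adjusted p = 0.00937), with all 7 KPC mice above the WT mean. That call was lost without KPC mice 40, 89, 145 and 154 (1.45, adjusted p = 0.0585) and with the acinar enzyme level as a covariate (0.95, adjusted p = 0.68). The acinar enzyme level itself differs between KPC and WT mice, so the loss with that covariate does not explain the difference. Between KPC ASC KO and KPC the Trp53 difference of -0.80 did not pass (adjusted p = 0.149), and without KPC ASC KO mouse 384 it was -1.46 and passed (adjusted p = 0.0185). The counts behind Trp53 were 1 to 4 per WT library.

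The comparison of KPC with WT pancreas asks what the KPC genotype changes in the organ at 20 weeks. In KPC pancreas, transcripts of acinar cells, the cells that make digestive enzymes, were lower, and transcripts of macrophages, fibroblasts and extracellular matrix were higher. The 28 acinar enzyme genes took 44.3% ± 3.44 (SD, n = 6) of all counts in WT and 14.7% ± 11.6 (SD, n = 7) in KPC mice. All 7 KPC mice (3.85% to 34.3%) lay below all 6 WT mice (40.5% to 49.8%) (exact permutation test, p = 0.00117, adjusted p = 0.00699). Macrophage transcripts summed to 749 ± 134 CPM (SD, n = 6) in WT and 4367 ± 1200 CPM (SD, n = 7) in KPC (exact permutation test, p = 0.00117, adjusted p = 0.00699). That sum is a share of all counts without TMM scaling, and with TMM scaling the macrophage genes rose by a median log2 change of 1.41. Of 6920 genes tested in edgeR, 2070 changed, 1023 of them higher and 1047 lower in KPC, and 766 and 599 of these by more than 2-fold. The lower genes with the largest changes were Tdh, a mitochondrial threonine dehydrogenase, which fell from 122 ± 46.0 CPM to 2.04 ± 2.63 CPM (log2 -6.40, SE 0.66, adjusted p = 2.17e-05), and Ctrc, the digestive enzyme chymotrypsin C (log2 -4.96, SE 0.61, adjusted p = 2.76e-05). Gal, the neuropeptide galanin, followed with a log2 change of -4.75 (SE 0.66, adjusted p = 0.000176), and Tmed11, a member of the family that carries cargo between the endoplasmic reticulum and the Golgi, with -4.58 (SE 0.58, adjusted p = 5.55e-05). Each of these 4 genes was lower in all 7 KPC mice than in any WT mouse. The higher genes with the largest changes were Thbs4, a matricellular thrombospondin (log2 3.19, SE 0.91, adjusted p = 0.0116), Lpxn, an adhesion adaptor of leukocytes (3.08, SE 0.71, adjusted p = 0.00297), and Ncf4, a subunit of the phagocyte NADPH oxidase (2.99, SE 0.80, adjusted p = 0.00801). Thbs4 lost its call in limma-voom (2.25, adjusted p = 0.0868). Without KPC mice 40, 89, 145 and 154, Lpxn (2.24, adjusted p = 0.0899) and Ncf4 (1.59, adjusted p = 0.252) lost theirs, and so did Ncf4 with the B cell level as a covariate (1.89, adjusted p = 0.0507).

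**Figure D1:**
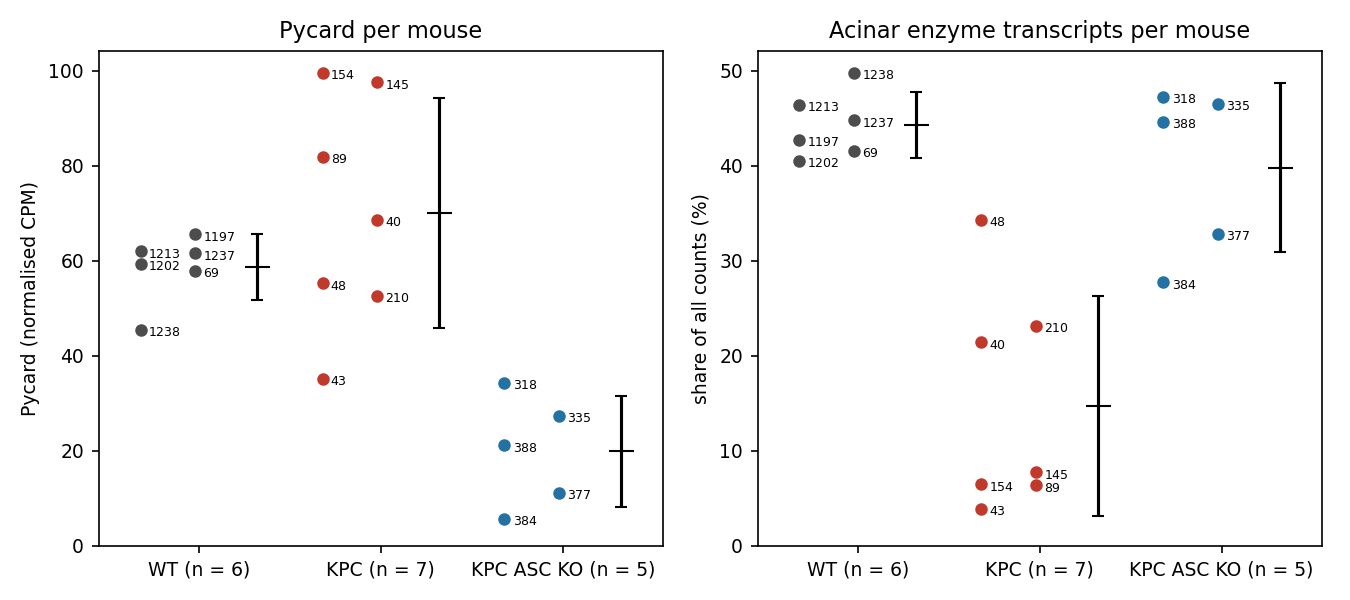
The left panel plots TMM-normalised CPM of Pycard and the right panel the percentage of all counts taken by 28 acinar enzyme genes, with 1 dot per mouse labelled by mouse number and a bar for the mean ± SD of each group. All 5 KPC ASC KO mice lie below all WT and KPC mice for Pycard, and KPC mice run from 3.85% to 34.3% in acinar enzymes against 40.5% to 49.8% in WT.

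Of the 36 lists tested, 15 passed for KPC against WT, 11 of them higher and 4 lower. Among the acinar enzymes, 26 of 28 genes fell and 2 did not pass, with a median log2 change of -2.53. This number was 26 adjusted over the list alone (fry adjusted p = 0.00368, adjusted p = 0.382 with an estimated correlation). Besides Ctrc, the pancreatic elastase Cela1 fell from 43303 ± 12100 to 4679 ± 5360 CPM (log2 -3.21, SE 0.64, adjusted p = 0.000994). Several of these enzymes belong to families of near-identical genes, among them the amylases, trypsins and Cela3a with Cela3b, so counts within a family are uncertain. All 16 tested genes of the acinar identity list, its transcription factors, receptors and granule proteins, fell by a median log2 change of -2.41. Members that passed numbered 16 adjusted over the list alone (fry adjusted p = 0.000434, adjusted p = 0.382 with an estimated correlation). Examples were Egf, the epidermal growth factor (log2 -3.47, SE 0.54), and Rab3d, a small GTPase of secretory granules (-1.85, SE 0.30). Of 18 endoplasmic reticulum chaperone and unfolded protein response genes, 9 fell and 9 did not pass, with a median log2 change of -0.76 that turned to 0.46 under scaling by total counts. The count was 9 adjusted over the list alone (fry adjusted p = 0.00735, adjusted p = 0.444 with an estimated correlation). They included the stress response transcription factors Atf4, at -1.03 (SE 0.21) and 0.24 under that scaling, and Xbp1, at -0.76 (SE 0.17) and 0.46. Of 16 mitochondrially encoded transcripts, 7 fell and 9 did not pass, with a median log2 change of -0.61 that turned to 0.71 under scaling by total counts. This number was 9 adjusted over the list alone (fry adjusted p = 0.0113, adjusted p = 0.444 with an estimated correlation). The first members were mt-Atp8 (log2 -1.59, SE 0.40), and the ribosomal RNA mt-Rnr1 (-0.98, SE 0.24, and 0.25 under that scaling).

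Several lists of stromal genes rose in KPC, while myofibroblastic fibroblast markers (3 of 9 higher, median 0.45, fry adjusted p = 0.605) and endothelial genes (1 of 10 higher, median 0.48, adjusted p = 0.26) did not pass. Of 26 extracellular matrix genes, 20 rose and 6 did not pass, with a median log2 change of 1.24. Members that passed numbered 22 adjusted over the list alone (fry adjusted p = 0.0412, adjusted p = 0.444 with an estimated correlation). The basement membrane collagen Col4a1 rose from 68.5 ± 14.5 to 159 ± 46.4 CPM (log2 1.22, SE 0.22, adjusted p = 0.000426), and the proteoglycan Bgn by 1.60 (SE 0.32, adjusted p = 0.00156). Fibroblast and stellate cell markers rose in 9 of 14 genes, with a median log2 change of 1.09 (11 adjusted over the list alone, fry adjusted p = 0.0173, adjusted p = 0.444 with an estimated correlation). They were led by the surface protein Thy1 (1.83, SE 0.29) and the collagen-binding proteoglycan Dcn (0.88, SE 0.18). Markers of inflammatory cancer-associated fibroblasts rose in 6 of 8 genes by a median of 1.56. The count was 6 adjusted over the list alone (fry adjusted p = 0.00733, adjusted p = 0.382 with an estimated correlation). In that list the complement component C3 stood at 465 ± 82.8 CPM against 160 ± 15.9 (log2 1.54, SE 0.23, adjusted p = 8.05e-05) and the alarmin Il33 rose by 1.78 (SE 0.40). Complement and acute phase genes, which also count C3, rose in 9 of 11 genes by a median of 1.44. This number was 10 adjusted over the list alone (fry adjusted p = 0.00733, adjusted p = 0.382 with an estimated correlation). Regulators and markers of epithelial-mesenchymal transition rose in 6 of 9 genes by a median of 1.45. Members that passed numbered 8 adjusted over the list alone (fry adjusted p = 0.00368, adjusted p = 0.382 with an estimated correlation). Its leading members, the intermediate filament Vim (1.41, SE 0.22) and the hyaluronan receptor Cd44 (1.62, SE 0.33), are also abundant in fibroblasts and leukocytes. The matrix list lost its call without any 1 of the 6 WT mice (adjusted p = 0.0611 to 0.0855) and without KPC mouse 40 (0.056), 48 (0.0535) or 210 (0.0558).

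Several lists of immune genes rose as well. Macrophage genes rose in 10 of 14 by a median log2 change of 1.41 (11 adjusted over the list alone, fry adjusted p = 0.00735, adjusted p = 0.382 with an estimated correlation). The growth factor receptor Csf1r rose by 1.64 (SE 0.30, adjusted p = 0.000426) and the complement subunit C1qc by 1.82 (SE 0.32, adjusted p = 0.000438). MHC class II genes, which present antigen to helper T cells, rose in 8 of 9 by a median of 1.56. The count was 9 adjusted over the list alone (fry adjusted p = 0.00735, adjusted p = 0.382 with an estimated correlation). The invariant chain Cd74 rose from 257 ± 29.3 to 979 ± 320 CPM (log2 1.93, SE 0.30, adjusted p = 0.000186), and H2-Aa by 1.54 (SE 0.25). Dendritic cell genes rose in 4 of 5 by a median of 2.04 (5 adjusted over the list alone, fry adjusted p = 0.0223, adjusted p = 0.382 with an estimated correlation). The transcription factor Irf8 rose by 2.07 (SE 0.55) and Fscn1, an actin-bundling protein of mature dendritic cells, by 2.04 (SE 0.61). All 7 tested cytokine and NF-kB target genes rose, by a median of 1.57. This number was 7 adjusted over the list alone (fry adjusted p = 0.0367, adjusted p = 0.444 with an estimated correlation). Those named first were regulators and an adhesion molecule, not cytokines: Icam1 (1.78, SE 0.37) and Relb (1.79, SE 0.45). Immediate early genes, which also respond to the handling of tissue, rose in 3 of 7 by a median of 1.10 (4 adjusted over the list alone, fry adjusted p = 0.0173, adjusted p = 0.382 with an estimated correlation). Junb rose by 1.37 (SE 0.32) and Zfp36 by 1.21 (SE 0.39). The cytokine list lost its call without any 1 of the 6 WT mice (adjusted p = 0.0561 to 0.0855), the dendritic cell list without WT mouse 1238 (0.0545), and the immediate early list without WT mouse 1202 (0.0511).

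Other innate immune lists did not pass in fry: interferon-stimulated (adjusted p = 0.069), interferon gamma (0.265), interleukin 1 family (0.26), nucleic acid sensing (0.478) and lytic cell death (0.764) genes. In the exact permutation test of scores per mouse, the interleukin 1 family (0.78, adjusted p = 0.004), nucleic acid sensing (0.59, adjusted p = 0.02) and interferon gamma (1.06, adjusted p = 0.036) lists were higher in KPC. Of the inflammasome genes other than Pycard, 5 were deep enough to test, and 2 of them rose (median log2 change 0.73, 2 adjusted over the list alone, fry adjusted p = 0.0033, adjusted p = 0.382 with an estimated correlation). These were Gsdmd, the pore-forming protein of pyroptosis (1.04, SE 0.36, adjusted p = 0.0324), and Nek7, a kinase that binds the sensor NLRP3 (0.73, SE 0.27, adjusted p = 0.0441). The Gsdmd call was lost without WT mouse 69 (adjusted p = 0.0834), 1197 (0.0558), 1202 (0.0785), 1213 (0.0683) or 1238 (0.0707). The Nek7 call was lost without WT mouse 69, 1197, 1202, 1237 or 1238 or KPC mouse 48, 89, 145, 154 or 210 (adjusted p = 0.0516 to 0.0946). Caspase 1 and its substrate interleukin 1 beta were too low to test: Casp1 had 1 count in all WT libraries together, 97 in KPC and 8 in KPC ASC KO, and Il1b had 8, 61 and 7. The sensors Nlrp3, with 0, 7 and 2 counts, and Aim2, with 2, 39 and 4, were left out by the filter on low counts as well, and these 4 genes were not tested. These are raw sums, and the KPC libraries are on average the deepest. In WT, KPC and KPC ASC KO, mean normalised CPM was 0.71, 8.23 and 3.99 for Casp1 and 6.25, 5.90 and 2.60 for Il1b. It was 0, 0.44 and 0.74 for Nlrp3 and 1.41, 3.93 and 1.48 for Aim2.

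Lymphoid transcripts differed widely among the KPC mice. B cell genes summed to 2712 CPM in mouse 40, 496 in mouse 43, 285 in mouse 48, 4850 in mouse 89, 5363 in mouse 145, 5245 in mouse 154 and 706 in mouse 210. They summed to 234 to 441 in WT and 352 to 862 in KPC ASC KO mice. The B cell list, with 6 of 11 genes higher at a median log2 of 2.05 (9 adjusted over the list alone), did not pass as a list (fry adjusted p = 0.423), although the summed CPM without TMM scaling passed (exact permutation test, p = 0.0256, adjusted p = 0.0486). Sums of T cell (adjusted p = 0.0469) and lymphoid stroma genes (adjusted p = 0.0478) passed the same exact test, and those of plasma cell genes did not (adjusted p = 0.0569). As a list in fry, plasma cell genes did not pass (6 of 12 higher, median 1.65, 10 adjusted over the list alone, adjusted p = 0.254). Lymphoid stroma genes did not pass in fry either (2 of 5 higher, median 1.25, 2 adjusted over the list alone, adjusted p = 0.478). The T cell list had too few tested genes for fry. Of 15 immunoglobulin and T cell receptor segments tested, 7 were higher in KPC and 0 were lower.

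**Figure D2:**
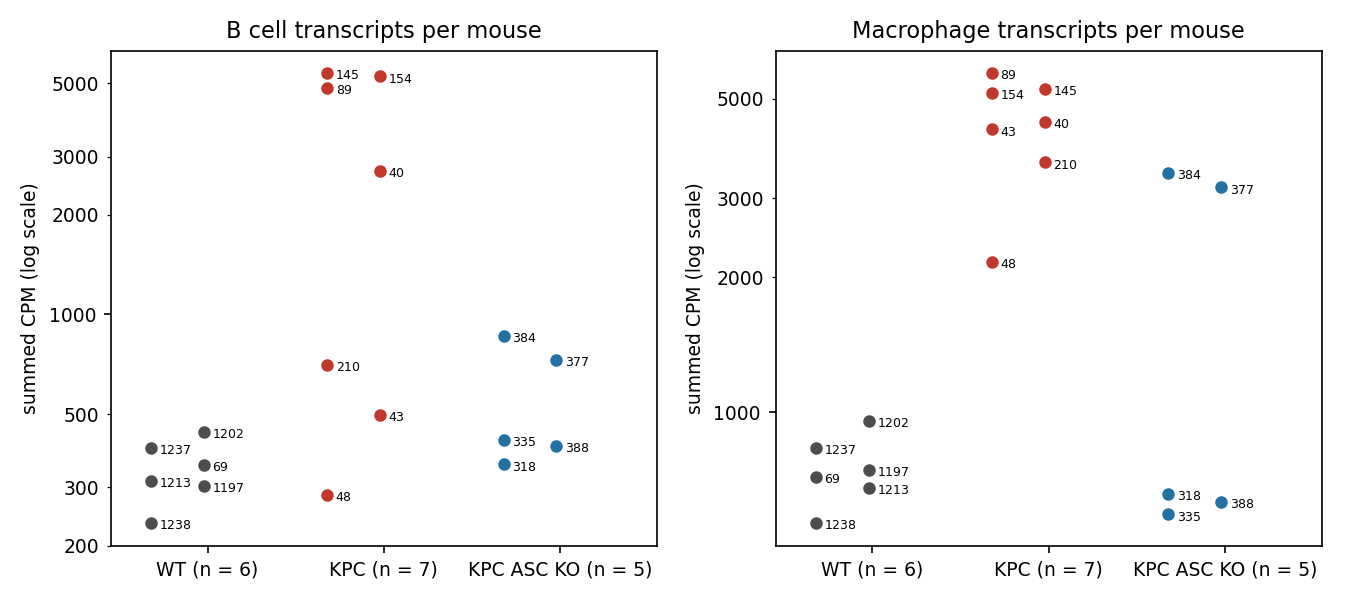
Summed CPM, without TMM scaling, of B cell genes (left) and macrophage genes (right) on log axes, with 1 dot per mouse labelled by mouse number. B cell values of KPC mice run from 285 to 5363 CPM against 234 to 441 in WT, and macrophage values of KPC ASC KO mice run from 592 to 3408 CPM.

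Without KPC mice 40, 89, 145 and 154, an alternative chosen after seeing the data, 728 genes were called for KPC against WT, 615 of them among the 2070. The median of the dendritic cell list was 0.27 (adjusted p = 0.337) and that of the MHC class II list 1.07 (adjusted p = 0.0765). The unfolded protein list (-0.57, adjusted p = 0.0823) and the mitochondrially encoded list (-0.42, adjusted p = 0.108) lost their calls too, so that 11 of the 15 list calls remained. With the acinar enzyme level of each mouse as a covariate, edgeR called 0 genes, with 628 at an unadjusted p under 0.05. Among the genes named first, log2 differences were 3.05 for Thbs4, 2.80 for Lpxn and 2.03 for Ncf4, and -2.90 for Tdh and -2.71 for Ctrc. The acinar enzyme share was lower in every KPC mouse than in any WT mouse, so this covariate largely overlaps with genotype. The 0 calls therefore cannot show that acinar content explains the differences. The difference between groups also moves with scaling, which is given with the other alternatives.

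**Figure D3:**
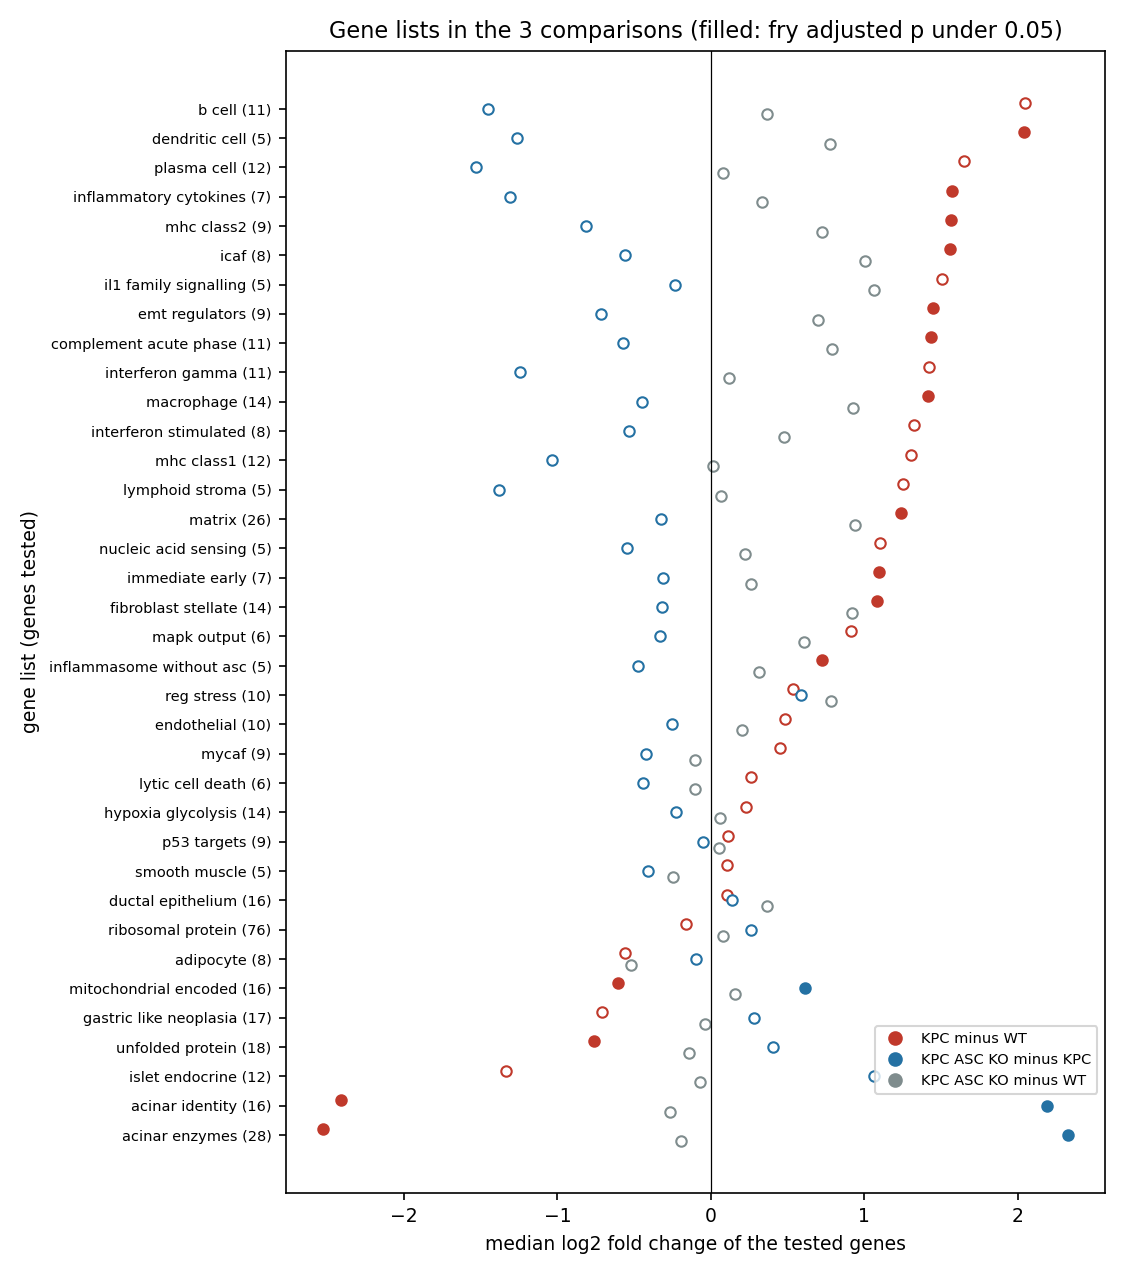
Median log2 fold change of the tested genes of 36 lists (number of genes in brackets) in the 3 comparisons, where filled dots have a fry adjusted p under 0.05. The acinar enzyme list lies at -2.53 for KPC minus WT, 2.32 for KPC ASC KO minus KPC and -0.20 for KPC ASC KO minus WT. The direction of the mitochondrially encoded and unfolded protein lists for KPC minus WT, and of the mitochondrially encoded list for KPC ASC KO minus KPC, turns under scaling by total counts.

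The comparison of KPC ASC KO with KPC pancreas asks what the loss of ASC changes in the KPC model. Acinar transcripts were higher in KPC ASC KO than in KPC pancreas, and macrophage transcripts took a smaller share of all counts. Acinar enzymes took 39.8% ± 8.91 (SD, n = 5) of counts in KPC ASC KO against 14.7% ± 11.6 (SD, n = 7) in KPC (exact permutation test, p = 0.00758, adjusted p = 0.0227). The TMM-scaled acinar enzyme score differed by 2.80 and did not pass over 48 lists (exact permutation test, p = 0.0101, adjusted p = 0.097). The shares were 47.3%, 46.5%, 32.8%, 27.7% and 44.6% in mice 318, 335, 377, 384 and 388. Macrophage genes summed to 1691 ± 1461 CPM (SD, n = 5) against 4367 ± 1200 CPM (SD, n = 7) (exact permutation test, p = 0.00884, adjusted p = 0.0245). This sum is a share of all counts without TMM scaling, and the TMM-scaled macrophage score differed by -0.73 and did not pass (exact permutation test, p = 0.053, adjusted p = 0.134). The sums were 656, 592, 3168, 3408 and 630 CPM in the same order of mice. Of 6920 genes tested in edgeR, 652 changed, 466 of them higher and 186 lower in KPC ASC KO, and 306 and 139 of these by more than 2-fold. The higher genes with the largest changes were Tdh, at 42.5 ± 32.3 against 2.04 ± 2.63 CPM (log2 4.75, SE 0.74, adjusted p = 0.00344), and Tmed11 (4.44, SE 0.58, adjusted p = 0.00124). Next came Amy2-ps1, an amylase pseudogene whose counts are uncertain (3.58, SE 0.81, adjusted p = 0.0141), and Hsbp1l1, a relative of a heat shock factor binding protein (3.49, SE 0.50, adjusted p = 0.00124). All 5 KPC ASC KO mice lay above the KPC mean for each of these 4 genes. Lower genes with the largest changes were Otulinl, a relative of a linear-ubiquitin protease (-2.94, SE 0.67, adjusted p = 0.011), and Ly6c2, a surface protein of monocytes (-2.40, SE 0.71, adjusted p = 0.0442). They were followed by Pik3cd, the leukocyte isoform of a phosphoinositide 3-kinase (-2.35, SE 0.48, adjusted p = 0.00632).

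The 3 lists that passed for KPC ASC KO against KPC were all higher. Acinar enzymes rose in 25 of 28 genes and 3 did not pass, by a median log2 change of 2.32. Members that passed numbered 26 adjusted over the list alone (fry adjusted p = 0.0257, adjusted p = 0.573 with an estimated correlation). Cela1 stood at 35641 ± 22636 against 4679 ± 5360 CPM (log2 2.93, SE 0.65, adjusted p = 0.00971) and Ctrl, a chymotrypsin-like protease, rose by 2.69 (SE 0.62, adjusted p = 0.0111). Acinar identity genes rose in 11 of 16 by a median of 2.19 (16 adjusted over the list alone, fry adjusted p = 0.00261, adjusted p = 0.573 with an estimated correlation). Among them were Egf (3.27, SE 0.54, adjusted p = 0.00344) and Rab3d (1.40, SE 0.31, adjusted p = 0.0111). Mitochondrially encoded transcripts rose in 6 of 16 by a median of 0.61, which turned to -0.51 under scaling by total counts. The count was 10 adjusted over the list alone (fry adjusted p = 0.0246, adjusted p = 0.573 with an estimated correlation). Its first members were subunits of the respiratory chain, mt-Nd4 at 0.84 (SE 0.18) and -0.32 under that scaling, and mt-Cytb at 0.83 (SE 0.20) and -0.33. Immune lists did not pass. MHC class I genes had a median of -1.03, with 3 of 12 lower (10 adjusted over the list alone, adjusted p = 0.197). MHC class II genes had -0.82, with 1 of 9 lower (8 adjusted over the list alone, adjusted p = 0.139). Cytokine and NF-kB target genes had -1.31, with 3 of 7 lower (6 adjusted over the list alone, adjusted p = 0.139). Macrophage genes had -0.45, with 2 of 14 lower (2 adjusted over the list alone, adjusted p = 0.211). The inflammasome genes other than Pycard had -0.48, with 0 of 5 called in edgeR (adjusted p = 0.139).

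The number of calls for KPC ASC KO against KPC rested on single mice: 1066 genes without KPC mouse 48, 314 without 89, 317 without 145, 326 without 154, and 226, 195 and 228 without KPC ASC KO mice 318, 335 and 388. The lists called numbered 7 without KPC mouse 43, and 1 without KPC mouse 154 or KPC ASC KO mouse 318, 335 or 388. The acinar enzyme list lost its call without KPC mouse 89 (adjusted p = 0.0535), 145 (0.0636) or 154 (0.0578) or KPC ASC KO mouse 318 (0.0738), 335 (0.0889) or 388 (0.0771), and the mitochondrially encoded list without KPC mouse 154 (0.0556) or those same 3 KPC ASC KO mice (0.0738, 0.0889 and 0.0771). The acinar identity list kept its call without any 1 mouse but lost it with only the compared groups in the fit (adjusted p = 0.0528), where 0 lists were called, and without KPC mice 40, 89, 145 and 154 (1.54, adjusted p = 0.0615). The gene mt-Cytb lost its call without KPC ASC KO mouse 318 (0.0505), and Ly6c2 without any 1 of the 5 KPC ASC KO mice or KPC mouse 40, 89, 145 or 154 (0.0577 to 0.114). Without KPC mice 40, 89, 145 and 154, chosen after seeing the data, 1 gene was called, at 912 genes with an unadjusted p under 0.05, and the median of the acinar enzymes was 1.68 (adjusted p = 0.083), while Ly6c2 turned to 0.25. With the acinar enzyme level as a covariate edgeR called 0 genes (233 unadjusted). Log2 differences were then -2.02 for Pycard, -2.24 for Otulinl and -2.08 for Pik3cd, and 1.44 for Tdh and 1.87 for Tmed11. The acinar enzyme share itself differed between these groups, so the 0 calls cannot show that acinar content explains the differences. Pycard stood at -1.94 without the covariate, so its call was lost at a similar log2 difference.

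The comparison of KPC ASC KO with WT pancreas asks what remains different from normal pancreas when ASC is lost in KPC mice. No gene passed, and the difference in the acinar enzyme share did not pass either, while the matrix, fibroblast, inflammatory fibroblast and macrophage lists had medians above WT, which 2 mice carried. Acinar enzymes took 39.8% ± 8.91 (SD, n = 5) of counts against 44.3% ± 3.44 (SD, n = 6), a difference that did not pass (exact permutation test, p = 0.31, adjusted p = 0.348). Mice 377 (32.8%) and 384 (27.7%) lay below all 6 WT mice (40.5% to 49.8%), and mice 318, 335 and 388 (44.6% to 47.3%) within their range. The basement membrane collagen Col4a1 came closest, at 169 ± 42.2 CPM (SD, n = 5) against 68.5 ± 14.5 CPM (SD, n = 6), a log2 difference of 1.33 (SE 0.24, adjusted p = 0.0642), with all 5 KPC ASC KO mice above all 6 WT mice. The next smallest p-values belonged to Gm5561 (-1.39, SE 0.26, adjusted p = 0.0744), Ctrc (-3.27, SE 0.65, adjusted p = 0.108), the ribosomal protein Rpl29 (-1.18, SE 0.24, adjusted p = 0.108) and the tropomyosin Tpm4 (1.11, SE 0.24, adjusted p = 0.132). Gm5561 and Rpl29 are near-identical copies, so counts of both are uncertain. In edgeR 0 genes were called, with 691 at an unadjusted p under 0.05, limma-voom called 0, limma-voom with sample quality weights 2 and DESeq2 8. No list passed in fry (smallest adjusted p = 0.46, with 2 lists under 0.05 unadjusted, and 10 lists called by camera at its preset correlation). Medians were 0.94 for matrix (2 of 26 adjusted over the list alone), 0.92 for fibroblast (6 of 14), 1.01 for inflammatory fibroblast (5 of 8) and 0.93 for macrophage genes (7 of 14), each at an adjusted p = 0.46, while myofibroblastic fibroblast markers (-0.11, adjusted p = 0.924) and endothelial genes (0.20, adjusted p = 0.877) lay near WT. Mice 377 and 384 carried the differences of those 4 lists: macrophage scores were 6.63 and 6.45 in them, and 5.19, 5.17 and 4.82 in mice 318, 335 and 388, within the WT range of 4.74 to 5.33. Matrix scores were likewise 6.22 and 6.40 in mice 377 and 384, and 4.99, 4.82 and 4.93 in the others, within the WT range of 4.55 to 5.09. For fibroblast genes (at least 6.80, highest WT mouse 5.78) and inflammatory fibroblast genes (at least 5.91, highest WT mouse 4.92) the same mice alone lay above WT. Leaving out WT mouse 69 or 1238 gave 1 called gene, and leaving out KPC ASC KO mouse 318 or 388 gave 2.

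The comparisons were then set against each other. Of the 2070 genes called for KPC against WT, 0 were also called for KPC ASC KO against WT, because the second comparison had none. Over 6920 genes, which are not independent replicates, the log2 fold changes of these comparisons had r = 0.669 and rho = 0.687. Simulated unchanged groups gave a mean r of 0.596 (0.577 to 0.613 in 50 simulations). There all 18 libraries, WT included, were simulated, with 1 mean per gene in all groups and genes drawn independently. The covariance was 0.322 against a simulated 0.0919, a difference of 0.230, and with the WT mice split so that each comparison had its own controls the median r was 0.368 (0.336 to 0.417 over 20 splits). Of the 2070 calls, 591 were also called in the opposite direction for KPC ASC KO against KPC: 438 genes lower in KPC against WT were higher in KPC ASC KO against KPC, where independent lists would share 70.5. Another 153 went the other way, where independent lists would share 27.5. Both comparisons use the KPC mice with opposite sign, so more reversed calls than in independent lists can arise from that alone. The 591 became 189 to 938 on leaving out 1 mouse and 1 without KPC mice 40, 89, 145 and 154. It was 218 with the B cell level and 0 with the acinar enzyme level as a covariate. The correlation across genes was r = -0.827 and rho = -0.778, against a simulated mean of -0.316 (-0.341 to -0.278) that comes from the simulated KPC libraries shared by both. The covariance was -0.526 against a simulated -0.0412, and with the KPC mice split into 3 and 4 the median was 152 reversed calls (0 to 378 over 35 splits) and the median r -0.728.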

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

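Every test of an explanation in this section was chosen only after the result had been seen. In 126 sets of mice of 1 group compared on 1 quantity, 5 single values stood apart from their group by Dixon's test, where chance at 1 in 20 gives 6.3. They were Trp53 in KPC ASC KO mouse 384 (33.4 CPM, next highest 15.6), the adipocyte score of KPC ASC KO mouse 377 (6.06, next 5.21), the plasma cell score of KPC ASC KO mouse 384 (7.03, next 6.62), the score of inflammasome genes other than Pycard in KPC mouse 210 (5.79, next 5.41) and the ribosomal protein score of WT mouse 69 (8.16, next 7.83).

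B cell transcripts were high in KPC mice 40, 89, 145 and 154. T cell, plasma cell and lymphoid stroma genes, 3 of 3 lists, were also higher in these 4 libraries than in the other 14, so lymph node or tertiary lymphoid tissue in the sampled piece is a likely source. After thinning to equal depth, the lowest of the 4 still had 2.99 times the B cell CPM of the highest other library. Random thinning leaves the expected share of counts unchanged, so this result cannot rule depth in or out. Without these mice the acinar enzymes were still lower in KPC than in WT by a median log2 change of -1.84 (fry adjusted p = 0.023), which rules out dilution by lymphoid RNA as the whole cause. Of the 35 ways to leave out 4 of 7 KPC mice, 5 gave 1 KPC ASC KO against KPC call or fewer. Each of these left out at least 3 of these mice and kept mice 48 and 210, and sets that left out at most 2 gave 84 to 1766 calls. Every set that left out mouse 48 gave at least 225 calls, with 225 to 366 where it also left out 3 of these mice. Calls were thus this few only where at least 3 of these mice were left out and mouse 48 was kept. The cause may lie in the mice left out, in the mice kept or in both.

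Transcripts of gastric surface mucosa, led by gastrokine 1 (Gkn1), were found in all 3 groups, with 836 counts in WT mouse 69 and 80 in WT mouse 1238, 402 to 974 in KPC and 218 to 595 in KPC ASC KO libraries. Precursor lesions of the KPC model, which can express gastric genes, are ruled out as the source in every library because 6 of 6 WT libraries lay above the share that carry-over between pooled libraries allows. Carry-over itself is ruled out as the only source, as 16 of 17 libraries lay above that share (exact Poisson test, Bonferroni-adjusted). The share was estimated from 4 genes with at least 75% of their counts in KPC mouse 43. Atp4a, Atp4b and Chia1 mark acid-secreting stomach mucosa in WT mouse 69 (95 counts), but had 10 counts in the other 17 libraries, 1.09% of the 919 that its ratio would give, which rules out such mucosa as the source in every library. Another source, such as neighbouring tissue without acid-secreting cells, may remain, and it was not tested. Gast, which encodes gastrin, had 51, 94, 18 and 19 counts in WT mice 69, 1197, 1202 and 1213, and 0 to 8 in every other library. The source may therefore differ between libraries.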

How the results depend on the processing

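Leaving out 1 mouse at a time gave 1745 to 2310 genes and 12 to 21 lists for KPC against WT, 195 to 1066 genes and 1 to 7 lists for KPC ASC KO against KPC, and 0 to 2 genes and 0 lists for KPC ASC KO against WT. Pycard stayed lower throughout, at a log2 of -2.29 to -1.65 against KPC and -2.02 to -1.38 against WT, and 0 to 2 calls were shared by the comparisons with WT. No named gene changed direction on leaving out a mouse.

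For KPC against WT, 5684 genes (96.9% higher, against 49.4%, with a median shift of 1.41 log2) and 30 lists were called under total counts, 1136 genes of 2391 under the stricter filter, 0 genes with the acinar covariate and 728 without KPC mice 40, 89, 145 and 154. Of the calls, 31.2% were higher in limma-voom, 60.0% under the upper quartile (shift 0.18) and 59.1% without a filter (shift 0.60). Camera with an estimated correlation called 0 lists and fry with quality weights 24. For KPC ASC KO against KPC, 1452 genes were called by limma-voom with quality weights, 5193 under total counts (2.73% higher, against 71.5%, shift -1.14), 265 with the compared groups only, 0 with the acinar covariate, 1 without those 4 KPC mice and 244 with the B cell covariate. Of the calls, 87.3% were higher in limma-voom, 55.7% without a filter (shift -0.41) and 55.3% under the stricter filter. Lists numbered 16 in camera at the preset correlation, 0 at an estimated one, 16 with quality weights, 28 under total counts, 0 with the compared groups only, 1 without the 4 mice and 6 with the B cell covariate.

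For KPC ASC KO against WT, genes called, and in brackets those shared with KPC against WT, were 8 (6) in DESeq2, 2 (2) in limma-voom with quality weights, 1 (1) under the upper quartile, 1 (1) under total counts (shift 0.24), 12 (9) without a filter, 5 (3) under the stricter filter, 7 (4) with the compared groups only, 3 with the acinar covariate, 4 (3) without the 4 KPC mice, 1 (1) after thinning and 8 (6) with the B cell covariate. Camera at the preset correlation called 10 lists. Pycard lost its call against KPC with the acinar covariate (-2.02) and without the 4 mice (-1.31, adjusted p = 0.144), and gained one against WT in DESeq2 (-1.68, adjusted p = 0.0368), without a filter (-1.63, adjusted p = 0.0089) and with the B cell covariate (-1.79, adjusted p = 0.0114).

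Under total counts the direction turned, for KPC against WT, in Atf4 (0.24), Xbp1 (0.46), Dnajc3 (0.13, and 0.062 with the acinar covariate), mt-Rnr1 (0.25), mt-Rnr2 (0.16), mt-Nd2 (0.63), the unfolded protein (0.46) and mitochondrially encoded (0.71) lists, and the scores of erythroid (0.047) and regulatory T cell (0.68) genes, and for KPC ASC KO against KPC in mt-Nd4 (-0.32), mt-Cytb (-0.33), mt-Nd1 (-0.38), mt-Nd2 (-0.46) and the mitochondrially encoded list (-0.51). Without the 4 KPC mice it turned in Ccr7 (-0.61) and the mesothelial score (-1.42) for KPC against WT and in Ly6c2 (0.25) for KPC ASC KO against KPC. The turns under total counts all go the way that the median log2 change of all genes moved under that scaling. That median was 1.41 for KPC against WT and -1.14 for KPC ASC KO against KPC. For the other alternatives, apart from fewer mice and fewer genes tested, the cause was not tested. Low depth limits WT most, and genes with few counts there are measured roughly.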

Other observations

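The tests of carry-over, of genes near Pycard and of splits of the mice were chosen only after the results had been seen, whereas the lists and their tests were fixed before the data were examined. Innate sensing and cell cycle genes too sparse for the list test also differed between KPC and WT pancreas when scored per mouse. PYHIN genes, which sense DNA, were higher in KPC (score difference 1.65 over 3 genes, exact permutation test, adjusted p = 0.0035), as were Toll-like and NOD-like receptor genes (0.94 over 4 genes, exact adjusted p = 0.00559). Proliferation genes scored 5.20 ± 0.64 in 7 KPC mice and 3.88 ± 0.54 in 6 WT mice (exact permutation test, adjusted p = 0.00883). Their scores were at least 5.17 in KPC mice 40, 89, 145 and 154, rich in lymphoid transcripts, and 4.42, 4.70 and 4.62 in KPC mice 43, 48 and 210, near the highest WT mouse at 4.68. Interferon-stimulated genes scored 1.09 higher (exact adjusted p = 0.00883) and MHC class I genes 1.10 higher (exact adjusted p = 0.0268), although neither passed as a list in fry (adjusted p = 0.069 and 0.0978). Islet genes had a median log2 difference of -1.34, with 3 of 12 lower (4 adjusted over the list alone), and did not pass in fry (adjusted p = 0.0911). Duct genes, at 0.10 with 2 of 16 changed, did not pass either (adjusted p = 0.998).

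Pycard counts that remain in KPC ASC KO libraries could come from carry-over between pooled libraries. The 5 libraries held 33 of 825 Pycard counts, or 4%, under the bound of 57.2 that carry-over allows, so carry-over and residual transcript cannot be told apart. The bound rests on 4 genes with at least 75% of their counts in KPC mouse 43. Expression of these genes in other libraries would count as carry-over, so the bound may be too high. DNA of the targeted chromosome that came along with the altered gene might change genes near Pycard. Genes within 15 Mb had a p under 0.01 for KPC ASC KO against WT in 2 of 158 cases (1.27%) and other genes in 198 of 6761 (2.93%), with a one-sided Fisher exact p of 0.947. The upper 95% bound of the nearby share was 4.50%, so an effect can be neither shown nor ruled out.

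Chance assignment of mice to groups is unlikely to explain the gene calls for KPC against WT, where 1 of 100 splits, the real one, reached 2070 genes (highest other 992). Chance is also unlikely for the lists, where again only the real split, 1 of 100, reached 15 (highest other 14). For KPC ASC KO against KPC, 3 of 100 splits reached 652 genes, the real one among them. The others set KPC mice 40, 89, 145 and 154 with mouse 43 (1353 genes) or 48 (767 genes) against all remaining mice. Both splits held only KPC mice on 1 side, and all KPC ASC KO mice with the remaining KPC mice on the other. They largely followed genotype, so they do not show that a grouping unrelated to genotype gives more calls than the real one. For lists, 13 of 100 splits reached 3, so chance may explain the count of lists. For KPC ASC KO against WT the real counts were 0 genes and 0 lists, which 100 of 100 splits reach by construction, so this test says nothing there.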
